A study of Elodea nuttallii and Chlamydomonas reinhardtii with 18 samples.

How the data were processed

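Stranded mRNA libraries (TruSeq kit, 300 ng of total RNA extracted with TRI-Reagent, per the labels) came from Elodea nuttallii shoots, the top 10 cm with the apex collected at a clean site, and from Chlamydomonas reinhardtii cells in mid-exponential growth in TAP medium diluted 4 times. Both were exposed in the River Olt for 2 h at 3 sites, with 3 libraries per site and organism. The submitters' processing notes name BWA 0.7.10, TopHat2 2.0.11, HTSeq 0.5.3p9 and edgeR 3.4.2, without saying which served which organism, and neither the genome build nor the annotation was given in the sources used here. The authors deposited 1 table of signal per organism, named as edgeR CPM per the file headers and names, in which each library is scaled by a factor of its own. The deposited comparison tables hold log2 fold changes and log2 mean CPM of the authors' comparisons of sites, per the file headers. They also hold the authors' p-value and FDR per feature, per the file headers, and their titles name a fold of 2 and an FDR of 5%. These tables list only features that the authors called changed.

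The plan assumed plain CPM. Because library totals depart from 1 common sum, the unit is treated as a scaled signal, and the planned test was kept. In every library 100% of the values lay within 0.01 of a whole number of reads once divided by the value of 1 read, estimated from the library's smallest values, so reads were recovered. Recovered depth was 2875062 to 7824727 reads in Elodea and 10322089 to 14097458 in Chlamydomonas, and 3 reads amount to 0.564 to 1.19 CPM in the Elodea libraries of Valcea. The main test was limma 3.58.1 in R 4.3.3 with a mean trend in the prior variance, on log2(CPM + 0.5) of features with at least 1 CPM in at least 3 of the 9 libraries of an organism. This left 56752 of 58110 Elodea transcripts and 13556 of 13566 Chlamydomonas genes. The 9 libraries shared 1 estimate of the spread, with no covariates. Changed means a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 2-fold, and an F-test covered the 3 sites together. Each organism was tested within its own table.

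The fit was tested on simulated data with 200 changed features per comparison. In Elodea 41.8%, 65.7% and 78.8% of features changed 3, 4 and 8 times were recovered for Babeni site 1 against Valcea, and 13.3% of the calls were false. For Babeni site 2 against Valcea these were 52.2%, 59.7% and 87.9%, with 8.9% false, and for the Babeni sites 47.8%, 65.7% and 75.8%, with 8.7% false. The simulated Elodea calls thus held more false ones than the nominal 5%. With 200 changed features, far fewer than were called in the real comparisons, such shares need not carry over to the real calls. In Chlamydomonas 73.1% to 98.5% were recovered, and 5.4%, 2.7% and 1.1% of the calls were false in the same order of comparisons.

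Elodea transcripts are numbered within 37036 assembled loci, of which 10057 have 2 or more transcripts. Transcripts of a locus share sequence, so the split of reads among them is uncertain, and sums per locus were an alternative added after seeing the data. Descriptions were taken from the authors' tables, which describe 4728 of 11717 transcripts over 2952 loci. Of these, 4685 transcripts over 2933 loci were tested. The 37 Elodea lists and 23 Chlamydomonas lists were fixed before the data were examined, as were the main test, its thresholds and most alternatives. The planned list test, camera, needs descriptions for all tested features and was not run for either organism. The Chlamydomonas lists were not used, since the files pair identifiers with no names. In Elodea, loci of a list that rose or fell were instead set against the other described loci by Fisher's exact test, 2-sided, for lists with at least 5 changed loci, a choice made after seeing the data. It was run on 26, 25 and 7 lists in the 3 comparisons and adjusted within each, and also over all 58 tests.

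Named transcripts were chosen by a rule fixed before the data were examined. Per comparison, among changed features whose 3 libraries of 1 site all lay above those of the other, it took the 8 largest increases and decreases with a mean of at least 5 CPM in the higher site and an informative description. It added up to 2 further members per list, at most 16. Where no names exist it allowed 2 identifiers that rose and 2 that fell. Exceptions are marked as chosen after their values were seen. Alternatives were other pseudocounts (0.1 and 2), other filters on low values, median centring, quantile normalization, no trend, adjusted p alone, the replicate number as a block, each library left out, fits of 2 sites only, and edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads. Thinning of reads to the smallest library was added after seeing the data. Overlap between comparisons that share the Valcea libraries was set against 20 simulations of unchanged groups and against independent lists. In each simulation all 9 libraries, those of Valcea included, were drawn anew, with 1 spread per feature at every site.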

Results

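RNA was sequenced from shoots of Elodea nuttallii, a submerged waterweed, and from cells of Chlamydomonas reinhardtii, a green alga, after 2 h in the River Olt. The title of the series names the toxicity of mercury in the field as the subject, and no mercury level was given in the sources used here. Each organism was exposed at Valcea, at Babeni site 1 and at Babeni site 2, with 3 libraries per site and 18 in all. The labels of the algal samples call Valcea the control. The Elodea libraries held 2875062 to 7824727 reads (median 4875382) over 58110 assembled transcripts. The shallowest was Valcea replicate 1, and the 3 libraries of Babeni site 2 were the deepest, with 6932366 reads or more. The Chlamydomonas libraries held 10322089 to 14097458 reads (median 11608628) over 13566 genes. Values are normalised read counts (CPM, scaled to library size), as mean ± SD with n = 3 libraries per site, and log2 differences on the log2(CPM + 0.5) scale carry their standard error (SE). This scale understates the change of low transcripts. A feature is said to have risen, fallen or changed where limma's Benjamini-Hochberg adjusted p was under 0.05 and the difference at least 2-fold. The labels do not say whether the libraries of a site came from separate plants or cultures, so p-values measure only the spread between these libraries, which may be technical.

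**Figure D1:**
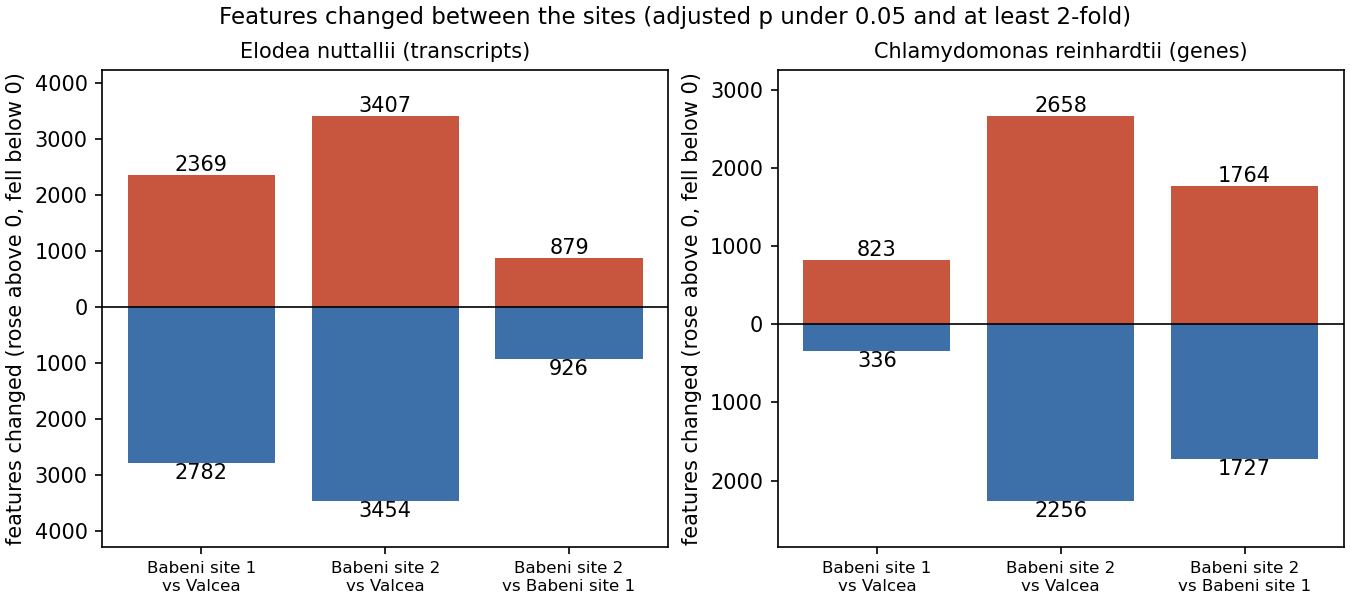
Number of features that rose (above 0) or fell (below 0) in each comparison of sites, for Elodea transcripts and Chlamydomonas genes, as bars. Between the 2 Babeni sites 879 Elodea transcripts rose and 926 fell, against 3407 and 3454 between Babeni site 2 and Valcea.

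The first comparison asked which Elodea transcripts differed between Babeni site 1 and Valcea. Among abundant described transcripts, the steepest falls were those of a guard cell anion channel of the SLAC1 type, a channel that releases anions when stomata close. Locus_5516_Transcript_4_5_ stood at 49.1 ± 6.04 CPM at Valcea and 0.525 ± 0.207 CPM at Babeni site 1, a log2 difference of -5.61 ± 0.27 (SE, limma adjusted p = 4.9e-09). A high affinity nitrate transporter fell from 344 ± 83.5 to 31.0 ± 4.13 CPM (Locus_1335_Transcript_18_19_, log2 difference -3.43 ± 0.17). Phenylalanine ammonia-lyase, the entry enzyme of phenylpropanoid synthesis, fell from 384 ± 61.9 to 67.4 ± 3.99 CPM (Locus_8893_Transcript_3_4_, -2.49 ± 0.16). A glyoxylate reductase fell from 215 ± 56.4 to 18.05 ± 0.443 CPM (Locus_395_Transcript_12_13_). Among the 8 largest increases of abundant described transcripts, a polygalacturonase-inhibiting protein, which blocks a wall-degrading enzyme of pathogens, rose from 1.02 ± 0.849 to 12.04 ± 3.002 CPM (Locus_1061_Transcript_1_1_, log2 difference 3.16 ± 0.34). A leucine-rich repeat receptor-like kinase rose from 4.33 ± 0.984 to 36.4 ± 4.60 CPM (Locus_2705_Transcript_30_33_), an RPM1-like disease resistance protein from 1.66 ± 1.18 to 15.0 ± 2.91 CPM (Locus_6486_Transcript_15_16_) and a wall-associated kinase from 3.51 ± 2.08 to 25.5 ± 7.20 CPM (Locus_13015_Transcript_1_1_). A transcript described as chloroplastic protochlorophyllide-like rose from 1.46 ± 0.910 to 11.99 ± 0.418 CPM (Locus_387_Transcript_3_4_).

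Lists of gene functions were fixed before the data were examined, but descriptions exist only for transcripts in the authors' deposited tables of changes. A list therefore holds transcripts chosen on these samples, and its count is not independent evidence of its direction. Changes were also common among described loci at large. Of 2933 tested, 748 fell and 693 rose outside the nitrogen assimilation list at Babeni site 1 against Valcea. A list can count many transcripts of 1 locus, so a count near such a share is no result about its function. Among 58 phenylpropanoid and flavonoid synthesis transcripts 32 fell, 7 rose and 19 did not pass at Babeni site 1 against Valcea, and adjusted over the list alone the counts were 32 and 7. Of 18 phosphate acquisition transcripts 14 fell (adjusted over the list alone 14), and the other 4 did not pass. Examples chosen after their values were seen are a PHO1-like phosphate transporter, from 47.4 ± 2.36 to 12.1 ± 2.57 CPM (Locus_14091_Transcript_2_3_), and a glycerol-3-phosphate transporter, from 32.9 ± 4.83 to 5.599 ± 1.144 CPM (Locus_3835_Transcript_1_1_). Of 44 antenna transcripts, which encode chlorophyll a/b binding proteins, 14 rose, 2 fell (1 without Valcea replicate 2 or Valcea replicate 3 or Babeni site 1 replicate 1) and the other 28 did not pass, with the same counts adjusted over the list alone. Among 60 antioxidant and thiol enzymes 20 fell and 8 rose (adjusted over the list alone 21 and 9), from 12 fallen and 5 risen loci. Dehydroascorbate reductase, which regenerates ascorbate, fell from 6.91 ± 0.802 to 1.43 ± 0.997 CPM (Locus_2581_Transcript_5_10_), and a low catalase transcript rose from 0.573 ± 0.323 to 4.16 ± 0.386 CPM (Locus_9527_Transcript_12_21_).

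Of 60 heat shock proteins and chaperones 21 fell and 2 rose at Babeni site 1 against Valcea (1 rose when any single library other than Valcea replicate 2 or 3 was left out). Adjusted over the list alone these counts were 21 and 3. By locus only 8 fell and 2 rose, with 747 fallen and 696 risen among the other described loci (Fisher's exact test, 2-sided, adjusted p = 0.288). A class III heat shock protein fell from 4.38 ± 2.04 to 0.932 ± 0.156 CPM (Locus_13103_Transcript_1_2_). Nitrogen assimilation had 22 of 44 transcripts fallen and 10 risen (adjusted over the list alone 23 and 10), and the risen ones numbered 3 without Valcea replicate 2 or Babeni site 1 replicate 3 and 4 without Babeni site 1 replicate 2. They came from 8 fallen and 5 risen loci. Starch and sucrose metabolism had 19 of 66 fallen and 10 risen (adjusted over the list alone 20 and 12), from 8 fallen and 3 risen loci. An invertase inhibitor fell from 2.77 ± 0.693 to 0.0638 ± 0.111 CPM (Locus_5604_Transcript_2_2_). An alkaline/neutral invertase, which splits sucrose, had no read at Valcea, where 3 reads amount to 0.564 to 1.19 CPM per library, and 1.78 ± 0.305 CPM at Babeni site 1 (Locus_9499_Transcript_3_4_, whose call a pseudocount of 2 ended). Metal transport and homeostasis had 4 of 14 risen (2 without Valcea replicate 2) and 5 fallen, with the same counts adjusted over the list alone, from 3 risen and 4 fallen loci. Members chosen after their values were seen are a ferric-chelate reductase, from 427 ± 31.8 to 186 ± 21.1 CPM (Locus_11791_Transcript_1_1_), a copper transporter, from 22.5 ± 7.15 to 8.47 ± 1.67 CPM (Locus_9365_Transcript_1_1_), and a metal tolerance protein, from 0.494 ± 0.187 to 2.13 ± 0.226 CPM (Locus_2223_Transcript_4_6_). Of 10 sulfur assimilation transcripts 4 fell, the same number adjusted over the list alone. Among them was ATP sulfurylase, the first enzyme of sulfate assimilation, from 85.3 ± 4.93 to 26.5 ± 2.503 CPM (Locus_9987_Transcript_1_1_, chosen after its values were seen).

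In all 5151 of 56752 tested Elodea transcripts changed between Babeni site 1 and Valcea by limma, 2369 rising and 2782 falling. By chi-square per transcript, on which abundant transcripts weigh most, Valcea replicate 3 of Elodea stood apart from replicates 1 and 2, with 12.41 or more against each, 2.45 between those 2 and at most 5.30 at the other sites. By correlation of log2 values it did not, with 0.918 to replicate 1 and 0.935 to replicate 2, against 0.934 between those 2. Without it 6765 transcripts changed at Babeni site 1 against Valcea and 8397 at Babeni site 2. By direction over loci, none of 26 lists passed Fisher's exact test (2-sided), the lowest adjusted p being 0.0504 for cytosolic ribosomal proteins and 0.0524 for phosphate acquisition. Of 31 ribosomal transcripts 14 fell (7 without Valcea replicate 2 or Babeni site 1 replicate 3 and 9 without Babeni site 1 replicate 1) and 1 rose (0 without any single library of Babeni site 1 or Valcea replicate 1 or 2), and adjusted over the list alone 19 and 1. Raw p was under 0.05 for 17061 transcripts. DESeq2 on recovered reads called 3324 transcripts, a pseudocount of 2 gave 2069, a minimum of 5 CPM 2436, and sums over the transcripts of a locus 3359 loci. On simulated data for this comparison, with only 200 changed transcripts, 13.3% of calls were false, above the nominal 5%.

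**Figure D2:**
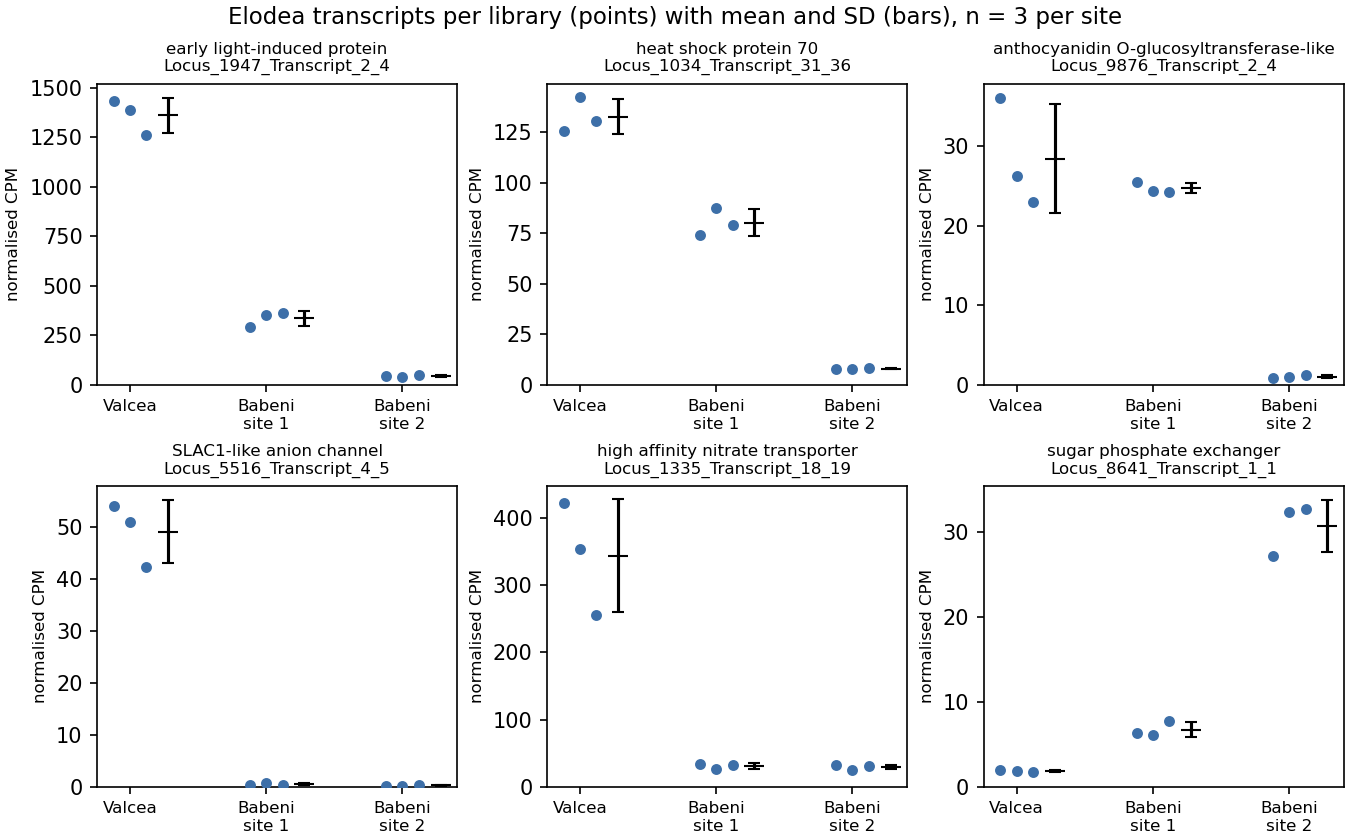
Normalised CPM of 6 Elodea transcripts in each of the 9 libraries (points), with the mean and SD of the 3 libraries per site. The early light-induced protein stood at 1360.3 ± 90.2, 334 ± 38.5 and 44.2 ± 6.37 CPM at Valcea, Babeni site 1 and Babeni site 2.

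Between Babeni site 2 and Valcea, the steepest fall among abundant described transcripts was again that of the SLAC1-like anion channel, with 0.264 ± 0.156 CPM at Babeni site 2 (Locus_5516_Transcript_4_5_, log2 difference -6.03 ± 0.27, limma adjusted p = 1.4e-10). An early light-induced protein, a chlorophyll-binding protein made under excess light, fell from 1360.3 ± 90.2 CPM at Valcea to 44.2 ± 6.37 CPM (Locus_1947_Transcript_2_4_, log2 difference -4.94 ± 0.13). Heat shock protein 70, a chaperone, fell from 35.7 ± 0.351 to 1.46 ± 0.413 CPM (Locus_1034_Transcript_29_36_, -4.23 ± 0.19). An ATL6-like ubiquitin ligase fell from 59.8 ± 11.6 to 1.57 ± 0.560 CPM (Locus_4126_Transcript_6_7_, -4.88 ± 0.20), and an anthocyanidin O-glucosyltransferase-like transcript from 28.5 ± 6.86 to 0.992 ± 0.168 CPM (Locus_9876_Transcript_2_4_). The nitrate transporter was at 29.3 ± 3.60 CPM (Locus_1335_Transcript_18_19_, -3.51 ± 0.17). The largest increase among abundant described transcripts was that of a sugar phosphate exchanger, from 1.86 ± 0.149 to 30.7 ± 3.08 CPM (Locus_8641_Transcript_1_1_, log2 difference 3.72 ± 0.19, limma adjusted p = 6.1e-10). A lectin-domain receptor kinase rose from 0.931 ± 0.398 to 14.1 ± 2.90 CPM (Locus_2161_Transcript_4_6_), and a hypersensitive-induced response protein from 2.52 ± 1.16 to 24.2 ± 1.63 CPM (Locus_1647_Transcript_12_13_). A LOB domain protein rose from 7.25 ± 1.67 to 62.6 ± 6.50 CPM (Locus_3435_Transcript_1_1_), and a thioredoxin h, a small protein that reduces disulfides, from 0.337 ± 0.0873 to 6.78 ± 1.72 CPM (Locus_11899_Transcript_3_6_).

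By list, again on transcripts chosen on these samples, phenylpropanoid and flavonoid synthesis had 39 of 58 transcripts fallen and 11 risen at Babeni site 2 against Valcea, with the same counts adjusted over the list alone. Heat shock proteins and chaperones had 37 of 60 fallen and 12 risen (adjusted over the list alone 38 and 12), from 14 fallen and 10 risen loci. Antioxidant and thiol enzymes had 32 of 60 fallen and 16 risen (adjusted over the list alone 33 and 16). A chloroplast peroxiredoxin, which removes peroxides, fell from 20.3 ± 5.37 to 2.57 ± 1.44 CPM (Locus_1574_Transcript_2_2_). Nitrogen assimilation had 22 of 44 fallen and 12 risen (7 without Babeni site 2 replicate 2; adjusted over the list alone 22 and 13). By locus 7 fell and 6 rose in it, with 872 fallen and 860 risen among the other described loci. Cell wall remodelling had 23 of 58 risen and 6 fallen (15 without Valcea replicate 3), with the same counts adjusted over the list alone. Within it an expansin, a wall-loosening protein, fell from 31.4 ± 7.10 to 3.70 ± 0.422 CPM (Locus_6290_Transcript_12_15_), and the polygalacturonase-inhibiting protein was at 5.84 ± 1.61 CPM (Locus_1061_Transcript_1_1_). Starch and sucrose metabolism had 22 of 66 risen and 16 fallen (adjusted over the list alone 22 and 18), but by locus 7 rose and 8 fell. Within it a sucrose synthase went from 1.36 ± 1.60 to 6.69 ± 2.37 CPM (Locus_8918_Transcript_8_10_).

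Calcium signalling had 23 of 51 transcripts risen (15 without Babeni site 2 replicate 1 and 14 without Babeni site 2 replicate 2) and 6 fallen at Babeni site 2 against Valcea, and adjusted over the list alone 26 and 6. Jasmonate signalling, a wound and defence hormone pathway, had 10 of 14 risen and 2 fallen (1 without Valcea replicate 1), and auxin signalling 15 of 32 fallen and 4 risen, all 4 counts being the same adjusted over the list alone. Metal transport and homeostasis had 9 of 14 fallen and 4 risen (2 without Valcea replicate 2; adjusted over the list alone 9 and 5). The ferric-chelate reductase of Locus_11791_Transcript_1_1_ was at 145 ± 29.2 CPM, and a heavy metal detoxification protein fell from 45.6 ± 8.05 to 13.5 ± 1.15 CPM (Locus_507_Transcript_18_21_, chosen after its values were seen). In all 6861 Elodea transcripts changed by limma, 3407 rising and 3454 falling. Among clock transcripts 9 of 10 pseudo-response regulators rose (8 without Valcea replicate 3) and 3 of 6 LHY-like transcripts, all of 1 locus, fell (1 to 3 with 1 library left out), and collection times were not given in the sources used here. None of 25 lists passed Fisher's exact test over loci (2-sided), the lowest adjusted p being 0.0971 for cell wall remodelling. A pseudocount of 2 gave 3313 changed transcripts, a minimum of 5 CPM 3308, and sums per locus 4543 loci. On simulated data for this comparison, with only 200 changed transcripts, 8.9% of calls were false.

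The 2 Babeni sites were then compared directly. Antenna transcripts were lower at Babeni site 2: 31 of 44 fell and the other 13 did not pass, and 32 fell adjusted over the list alone. One abundant member, chosen after its values were seen, stood at 473 ± 65.1 CPM at Valcea, 748 ± 14.0 CPM at Babeni site 1 and 359.7 ± 9.98 CPM at Babeni site 2 (Locus_303_Transcript_12_13_). Heat shock protein 70 fell from 80.3 ± 6.85 CPM at Babeni site 1 to 7.91 ± 0.313 CPM at Babeni site 2 (Locus_1034_Transcript_31_36_, log2 difference -3.26 ± 0.13, limma adjusted p = 2.4e-10). A heme-binding-like chloroplast protein fell from 40.8 ± 6.29 to 1.93 ± 0.490 CPM (Locus_15194_Transcript_4_6_, -4.10 ± 0.20), and the anthocyanidin O-glucosyltransferase-like transcript from 24.7 ± 0.645 to 0.992 ± 0.168 CPM (Locus_9876_Transcript_2_4_, -4.09 ± 0.19). A COP1-like ubiquitin ligase, whose relatives repress light responses in the dark, fell from 9.08 ± 2.35 to 0.751 ± 0.290 CPM (Locus_10139_Transcript_1_2_). The sugar phosphate exchanger rose from 6.72 ± 0.887 to 30.7 ± 3.08 CPM (Locus_8641_Transcript_1_1_), a CCT motif protein from 1.07 ± 0.271 to 6.29 ± 0.837 CPM (Locus_4292_Transcript_6_10_), and a bZIP63 transcription factor from 3.86 ± 0.696 to 17.3 ± 2.13 CPM (Locus_2290_Transcript_5_9_).

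By locus, 9 antenna loci fell and none rose between the Babeni sites, against 234 fallen and 185 risen loci among the other described ones (Fisher's exact test, 2-sided, p = 0.00621, adjusted over 7 lists p = 0.0435). This test was chosen after the data were seen, and 58 such tests were run over the 3 comparisons. Adjusted over all 58 tests its p is 0.0901, so the list does not pass over all tests run, and its members were chosen on these samples. The named antenna transcripts Locus_10014_Transcript_2_4_ and Locus_446_Transcript_7_13_ had log2 differences of -1.83 ± 0.34 and -1.69 ± 0.29. Of 60 heat shock proteins and chaperones 13 fell, all from 3 loci, and 1 rose (4 without Babeni site 1 replicate 2), with the same counts adjusted over the list alone. Starch and sucrose metabolism had 8 of 66 risen (5 without Babeni site 1 replicate 3 or Babeni site 2 replicate 1) and 5 fallen, and adjusted over the list alone 10 and 8. By locus 4 rose and 4 fell in it. An inactive beta-amylase rose from 7.72 ± 1.71 to 23.2 ± 3.36 CPM (Locus_4710_Transcript_5_8_), and a granule-bound starch synthase, which makes amylose, fell from 2.88 ± 0.778 to 0.506 ± 0.0760 CPM (Locus_256_Transcript_11_15_, whose call a pseudocount of 2 ended). A heat stress transcription factor B-2b fell from 3.15 ± 1.44 to 0.331 ± 0.476 CPM (Locus_18464_Transcript_3_4_).

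In all 1805 Elodea transcripts changed between the 2 Babeni sites by limma, 879 rising and 926 falling. Over the 3 sites 12555 transcripts differed by limma's F-test. A pseudocount of 2 gave 1054 changed transcripts between the Babeni sites and a minimum of 5 CPM 1104. On simulated data for this comparison, with only 200 changed transcripts, 8.7% of calls were false.

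**Figure D3:**
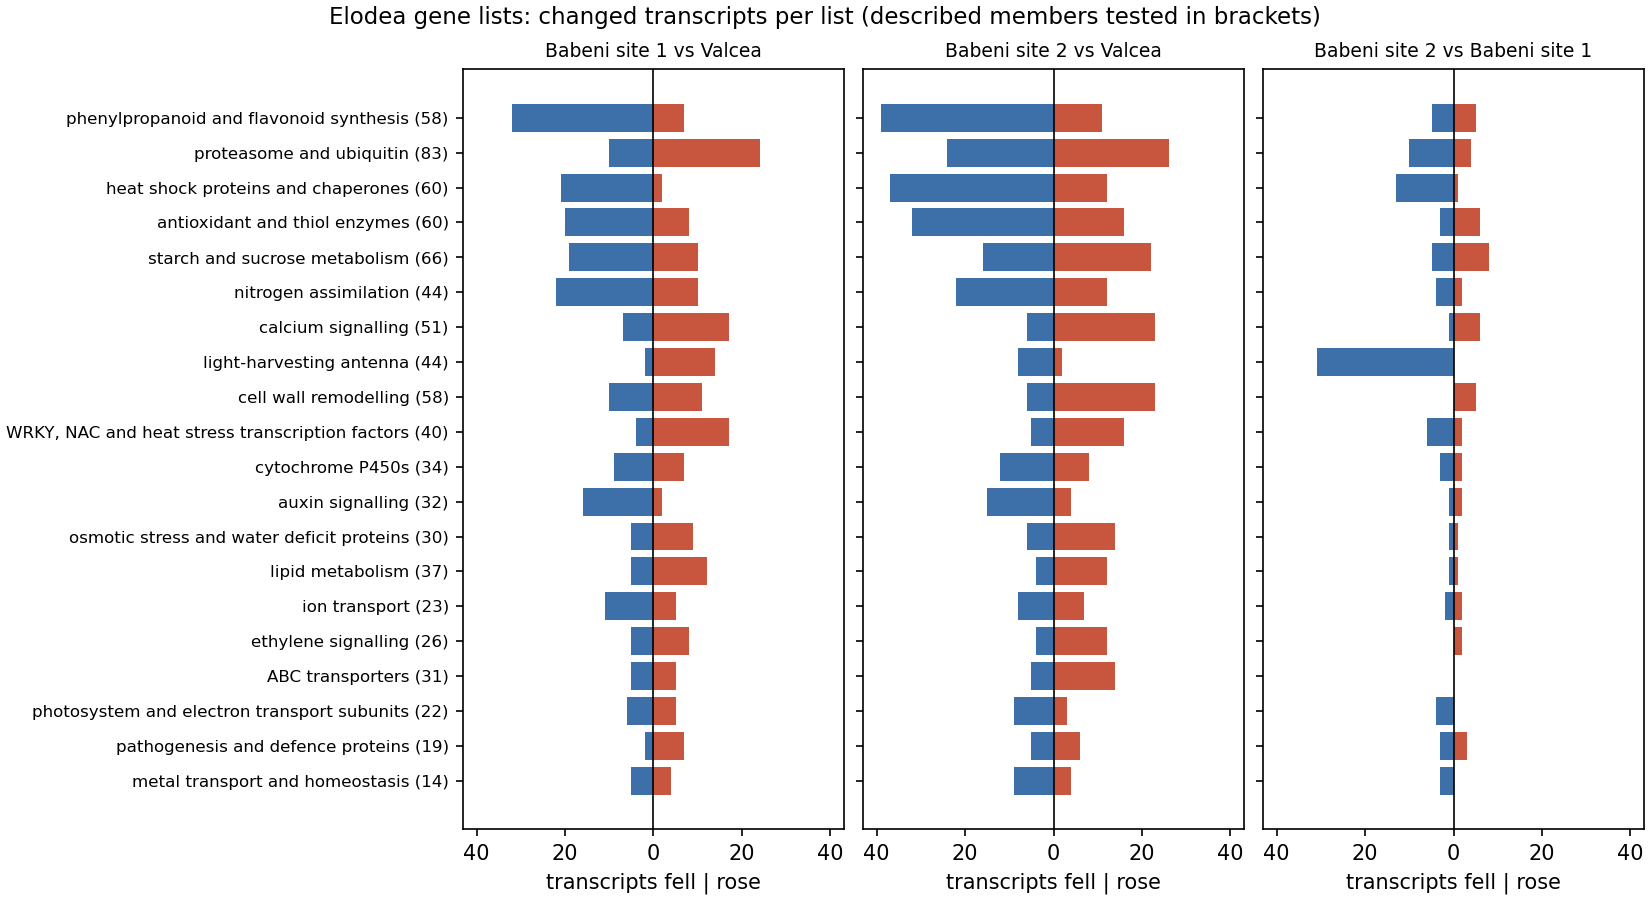
Described Elodea transcripts that fell (left of 0) or rose (right of 0) in the 20 lists with the most changes, for the 3 comparisons of sites, with the number of tested members in brackets. Between the Babeni sites 31 of 44 antenna transcripts fell, and 32 and 39 of 58 phenylpropanoid transcripts fell at Babeni site 1 and site 2 against Valcea.

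The changes at the 2 Babeni sites against Valcea overlapped in Elodea. At both sites 1270 transcripts rose and 1710 fell, where independent lists would share 142.2 and 169.3. Unchanged groups, simulated with the Valcea libraries drawn anew as well, shared 0.3 on average over 20 simulations. This value holds no effect in either comparison and does not measure how shared controls act among changed transcripts. The covariance of the 2 sets of log2 differences across transcripts was 0.382 against 0.052 simulated, and the correlation 0.747 against 0.5, with transcripts not independent replicates. A simulated correlation near 0.5 follows from the shared group alone and is not measured on these controls. The 3 Valcea libraries were not divided between the 2 comparisons, so part of the excess may come from the shared controls. A pseudocount of 2 gave an overlap of 1302 in place of 2980. The authors' deposited tables called 6217, 8700 and 2843 transcripts for Babeni site 1 against Valcea, Babeni site 2 against Valcea and the Babeni sites, and limma called 4949, 6759 and 1794 of these in the same direction and 0 in the opposite one.

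In Chlamydomonas more genes changed at Babeni site 2 than at Babeni site 1. The files pair the gene identifiers with no names, so functions are not described and only extremes are given. Gene Cre17.g727300 stood at 0.592 ± 0.163 CPM at Valcea, 0.357 ± 0.164 CPM at Babeni site 1 and 179 ± 6.26 CPM at Babeni site 2 (log2 difference of site 2 to Valcea 7.37 ± 0.21, limma adjusted p = 2.5e-09). Gene Cre05.g238650 stood at 5.43 ± 0.912, 39.6 ± 27.5 and 681 ± 25.4 CPM at the same sites (log2 difference 6.85 ± 0.54). The steepest falls were those of Cre05.g248400, from 942 ± 307 to 0.897 ± 0.285 CPM (-9.36 ± 0.68), and Cre05.g248450, from 753 ± 213 to 0.975 ± 0.247 CPM (-8.97 ± 0.80). At Babeni site 1 the genes Cre05.g248400 and Cre05.g248450 had an SD above their mean, 434 ± 546 and 249 ± 358 CPM.

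Between Babeni site 2 and Valcea 4914 of 13556 Chlamydomonas genes changed by limma, 2658 rising and 2256 falling, and 800 rose and 438 fell at least 4-fold. Between Babeni site 1 and Valcea 1159 changed, 823 rising and 336 falling, of which 86 and 33 at least 4-fold. Between the Babeni sites 3491 changed, 1764 rising and 1727 falling, and over the 3 sites 9118 differed by limma's F-test. The 3 libraries of Babeni site 1 differed most among themselves, with a chi-square per gene of 59.9 to 83.2 between pairs, against 2.16 to 6.30 at Babeni site 2 and 24.5 to 55.3 at Valcea. One gene took 7.75%, 4.48% and 1.41% of the reads of the Valcea libraries. With a pseudocount of 2 the genes changed between Babeni site 1 and Valcea numbered 711.

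At both Babeni sites against Valcea 551 Chlamydomonas genes rose and 220 fell, where independent lists would share 161.4 and 55.9 and simulated unchanged groups shared 0.05 on average. The covariance of the log2 differences across genes was 0.441 against 0.03 simulated, and the correlation 0.58 against 0.498. That simulated correlation too follows from the shared group, and the simulation gave all sites the same spread, unlike these libraries. Part of the excess may come from the shared controls, and a pseudocount of 2 gave an overlap of 449 in place of 771. The authors' deposited tables called 1610, 5485 and 3978 genes for Babeni site 1 against Valcea, Babeni site 2 against Valcea and the Babeni sites, and limma called 1133, 4912 and 3449 of these in the same direction and 0 in the opposite one.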

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

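The counts of other groupings of the libraries were made after the results were seen, and the direct comparison of the Babeni sites was planned. A gene can be called in opposite directions at the 2 Babeni sites against the same Valcea libraries, as 30 Chlamydomonas genes were: 12 rose at Babeni site 1 and fell at Babeni site 2, and 18 the reverse. In Elodea 8 transcripts were, 7 rising at Babeni site 1 and falling at Babeni site 2 and 1 the reverse. The direct limma comparison of the 2 Babeni sites passed for all of these as well, which opposite calls in 1 fit nearly force, so it adds no support. The 1 transcript, Locus_65489_Transcript_3_5_, has no description, was chosen after its values were seen, and stood at 2.94 ± 0.226, 0.979 ± 0.346 and 7.36 ± 0.861 CPM at Valcea, Babeni site 1 and Babeni site 2 (mean ± SD, n = 3). Its log2 differences to Valcea were -1.24 and 1.19.

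Other groupings of the same libraries into groups of 3 were refitted. For a comparison of 2 sites there are 10 splits, too few for a share under 0.1, and in each of the 6 comparisons only 1 split, the real one, gave as many features. In Elodea the real and the highest other counts were 5151 and 5 for Babeni site 1 against Valcea, 6861 and 1 for Babeni site 2 against Valcea, and 1805 and 3 for the Babeni sites. In Chlamydomonas they were 1159 and 0, 4914 and 0, and 3491 and 0. Every other split mixes libraries of both sites in each group, so a site difference partly cancels and widens the spread. Counts near 0 are then nearly forced and do not measure chance. Over the 3 sites, 1 of 100 splits drawn from 280, the real one, gave as many features: 12555 against at most 6087 in Elodea, and 9118 against at most 6583 in Chlamydomonas. The real grouping thus stood above the others drawn, which mix the sites as well. Chance differences between single exposures are not excluded by this, as the libraries of a site may be technical.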

How the results depend on the processing

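Sums per locus, thinned reads and the Fisher test of lists with both its adjustments were chosen after seeing the data, the other settings before. Counts of changed features not given here stayed within 1.5 times the main value. With a pseudocount of 2, Chlamydomonas genes changed between Babeni site 1 and Valcea numbered 711 and the overlap of the Babeni sites 449. In Elodea that setting gave 2069, 3313 and 1054 changed transcripts (Babeni site 1 against Valcea, Babeni site 2 against Valcea, Babeni site 2 against site 1), 6407 calls shared with the deposited tables (main 13502) and an overlap of 1302. A minimum of 5 CPM gave 2436, 3308 and 1104 in Elodea, with fewer transcripts tested. Adjusted p alone gave 3229, 8538 and 6974 in Chlamydomonas with an overlap of 2419, and 9260, 11340 and 2917 in Elodea with an overlap of 5890, because it drops the 2-fold minimum. DESeq2 gave 3324 for Elodea at Babeni site 1 against Valcea, and sums per locus gave 3359 and 4543 against Valcea, with fewer features. The cause of the pseudocount and DESeq2 shifts was not tested. Leaving out 1 library gave 947 to 1417, 4882 to 4954 and 3290 to 3825 changed Chlamydomonas genes, 8028 to 9985 differing among sites, 633 to 920 in the overlap and 9078 to 9489 shared with the deposited tables. In Elodea the ranges were 4080 to 6765, 5479 to 8397 and 1250 to 2116, with 9715 to 14053 among sites, 2487 to 4294 in the overlap and 11169 to 13385 shared. To look for pairing, the deviations of each library from the mean of its own site, on the log2 scale, were correlated between sites. These deviations correlated at -0.156 to 0.235 for same-numbered libraries and at -0.202 to 0.169 for the others, which does not settle whether the numbers pair them. Between Valcea and Babeni site 1 of Chlamydomonas same-numbered libraries were at 0.064, 0.235 and 0.081, and the others at -0.202 to 0.089. The Elodea numbers are those of the sample titles, and the sample names carry partly other numbers. With the replicate number as a block the counts were 1183, 4917 and 3509 in Chlamydomonas and 4855, 6583 and 1670 in Elodea. Of 180 list counts above 0, a pseudocount of 2 moved 123 by over 1.5 times and a minimum of 5 CPM 98, all to lower counts, thinned reads 51 (49 lower) and DESeq2 42 (41 lower). Mostly to higher counts went the moves of edgeR, 20 (6 lower), and of leaving out Valcea replicate 3, 20 (7 lower). Of the list counts printed, thinning at Babeni site 1 against Valcea moved the risen of heat shock from 2 to 1, of metal transport from 4 to 2 and of nitrogen assimilation from 10 to 4 and of the cytosolic ribosome from 1 to 0, and the fallen of the antenna from 2 to 1. At Babeni site 2 it moved the risen of heat shock from 12 to 7, of metal transport from 4 to 2 and of auxin signalling from 4 to 2. Between the Babeni sites it moved the fallen of the circadian clock, the 3 LHY-like transcripts and 1 regulator, from 4 to 1 and the risen from 2 to 1. It ended the fall of the 1 transposon at Babeni site 1 and of the 4 aquaporins at Babeni site 2. The 108 named pairs of feature and comparison, in which some features recur, were followed under part of the alternatives. These were the other pseudocounts, median centring, quantile normalization, the block and each library left out. Of these 1512 values 1479 stayed past the threshold, 33 from 12 features did not, and 0 reversed. Left-out libraries ended the call of Locus_105_Transcript_14_15_ (Babeni site 1 replicate 2 or 3), Locus_12853_Transcript_2_2_ (Valcea replicate 2), Locus_7602_Transcript_2_6_ (Babeni site 2 replicate 3), Locus_7565_Transcript_4_6_ (Babeni site 1 replicate 1 or 2, Babeni site 2 replicate 2 or 3), Locus_11899_Transcript_3_6_ between the Babeni sites (Babeni site 1 replicate 3, Babeni site 2 replicate 2 or 3), and Locus_10_Transcript_38_48_ and Locus_10_Transcript_46_48_ (replicate 1 or 3 of either Babeni site). The block also ended that of Locus_10_Transcript_38_48_. The other losses came with a pseudocount of 0.1 or 2, the only cause for Locus_9499_Transcript_3_4_, Locus_8837_Transcript_1_2_, Locus_256_Transcript_11_15_, Locus_1608_Transcript_5_11_ and Locus_1608_Transcript_7_11_. The planned list test and its alternatives were not run. Depth limits low transcripts, since 3 reads reach 1.19 CPM in the shallowest Elodea library.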

Other observations

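Of the tests weighed here, those of the 100 most abundant genes and of the shared axis of ribosomal-RNA-like transcripts were set down before their results were seen, and the others after. Of 13 described aquaporins, or water channels, of Elodea 3 rose, all TIP2-1 of the tonoplast and of 1 locus, and 6 fell, all of the plasma membrane type and 4 of them of Locus_1066, at Babeni site 1 against Valcea. Babeni site 2 had 4 risen, all of the TIP2-1 locus, and 4 fallen (2 without Valcea replicate 1 or Babeni site 2 replicate 1, 0 without Valcea replicate 2 and 1 without Babeni site 2 replicate 2 or Babeni site 2 replicate 3), 3 of the plasma membrane type and 1 NIP5-1-like (Locus_17609_Transcript_4_6_). Counts adjusted over the list alone were the same. They are transcripts chosen on these samples, and those named were chosen after their values were seen. The tonoplast aquaporin TIP2-1 rose from 33.6 ± 1.98 CPM at Valcea to 81.9 ± 3.84 CPM at Babeni site 1 and 77.3 ± 11.9 CPM at Babeni site 2 (Locus_7450_Transcript_4_8_). A plasma membrane aquaporin stood at 116 ± 18.6, 48.7 ± 9.12 and 67.4 ± 6.40 CPM at the same sites and fell at Babeni site 1 (Locus_1066_Transcript_11_16_). A fucoxanthin chlorophyll a/c binding protein, a kind found in diatoms and related algae rather than in plants, fell from 20.9 ± 1.12 CPM at Valcea to 9.59 ± 1.39 and 7.94 ± 0.923 CPM at the Babeni sites (Locus_12779_Transcript_1_1_, the only described transcript of its list). Of 11 described transposon transcripts 5 rose and 1 fell at Babeni site 1 against Valcea (risen and fallen adjusted over the list alone 5 and 2; fallen: 0 without Valcea replicate 1 or Babeni site 1 replicate 1 or Babeni site 1 replicate 2 and 2 without Valcea replicate 3).

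Of 44 antenna transcripts of Elodea 31 fell at Babeni site 2 against Babeni site 1, a list that does not pass Fisher's exact test adjusted over all tests run. Shared reads among transcripts of a locus are argued against by 9 fallen and 0 risen loci, and depth by 27 of the 31 fallen transcripts still passing with every library thinned to the smallest. Reads shared between loci were not tested, so the 9 loci need not be independent. A different time of day of collection stays open, as the clock transcripts do not decide it. The median log2 difference between the Babeni sites was -1.10 for LHY-like transcripts, a morning clock gene (6 transcripts of 1 locus, 3 fell), and 0.99 for pseudo-response regulators of the later day (10 transcripts of 3 loci, 2 rose and 1 fell). The risen CCT motif transcript Locus_4292_Transcript_6_10_ (log2 difference 2.12 ± 0.28) shares a locus with some of these regulators but is outside this count. With 1 library left out 1 to 3 LHY-like transcripts fell, 0 to 3 regulators rose and 0 to 1 fell, while the medians ran from -1.26 to -0.80 and from 0.93 to 1.05. Thinned reads gave the clock list 1 fall in place of 4 and 1 rise in place of 2, as counts only. At Babeni site 2 against Valcea the medians were -1.08 and 1.54, yet only 8 of 44 antenna transcripts fell (5 without Valcea replicate 1 or Babeni site 2 replicate 2) and 2 rose. At Babeni site 1 against Valcea they were -0.09 and 0.59, and 14 antenna transcripts rose. The most abundant LHY-like transcript stood at 90.1 ± 10.3, 68.1 ± 10.9 and 15.9 ± 1.01 CPM at Valcea, Babeni site 1 and Babeni site 2 (Locus_408_Transcript_39_41_, chosen after its values were seen). Neither collection time nor light was given in the sources used here, so a difference between the sites themselves is as open and untested.

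The Chlamydomonas libraries of Babeni site 1 spread widely among themselves. Mixing of Valcea-like and Babeni site 2-like RNA is argued against: the 132 genes that fell at least 8-fold between those sites had gone a median fraction of 0.772, 0.557 and 0.283 of the way in the 3 libraries, the 202 that rose 0.047, 0.048 and 0.072, and the smallest difference was 0.211 (95% bootstrap interval over genes 0.151 to 0.281). This interval treats genes as independent and measures no spread between libraries. The genes were chosen on the same Valcea and Babeni site 2 values that set the fractions, which can shift them. A few abundant genes are argued against, since without the 100 most abundant genes the smallest chi-square per gene of the Babeni site 1 pairs was 36.49, with at most 16.04 at the other sites. A difference in depth is argued against as the whole cause: in 20 thinnings of every library to 10322089 reads the smallest chi-square per gene was 48.11 at Babeni site 1, with at most 44.55 at Valcea and 6.05 at Babeni site 2. No biological explanation was tested, as the labels give the 3 libraries no difference.

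In Elodea 28 transcripts were taken as ribosomal-RNA-like. They were described as rRNA intron-encoded, chk1 checkpoint, senescence-associated or cell wall-associated hydrolase. Only the rRNA intron-encoded description names ribosomal RNA, and that the others derive from it is an untested assumption. Of these 28 transcripts 5 rose at Babeni site 2 against Babeni site 1, 4 of them from Locus_10, and 11 fell at Babeni site 1 against Valcea, 7 of them from Locus_10. They took 0.308% to 2.00% of the reads, with 1.736%, 2.00% and 0.312% in the 3 Valcea libraries. If these transcripts are ribosomal RNA, its carry-over in varying amounts between libraries may account for this. Of the within-site variance of their 13 loci 92.7% lay on 1 axis, against a 95th percentile of 85.6% in 1000 random sets matched on mean level. A difference between the sites stays open as well and was not tested.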
